A study of Mus musculus with 10 samples.

How the data were processed

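RNA was measured in the striatum of mice of the Chat-TRAP line DW167, in which a green fluorescent protein fused to the ribosomal protein Rpl10a marks the ribosomes of cholinergic neurons. Per the labels' protocols, tagged polysomes were immunopurified from homogenised whole striatum with antibodies against the fluorescent protein, and the RNA bound to them was extracted. Immunopurified libraries came from saline self-administration, cocaine self-administration and yoked control animals, with 3 libraries per group, and 1 further library was made from total RNA of saline animals without immunopurification (the input). The labels do not say whether a library came from 1 animal or a pool, or what the yoked animals received.

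The deposited values are raw read counts per gene symbol, 1 table per library, without normalisation. STAR 2.0.0e, HTSeq (no version given) and the mouse genome build mm10 are named in the submitters' processing notes. The gene annotation, the strand setting and any read filter are not stated there. The deposited count tables also hold reads that were not assigned to a gene, which were used here only as shares of all reads in each library. Each table listed 32531 gene symbols, of which 22961 matched the reference gene table of the same assembly, which supplied the coordinates. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart.

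Gene counts per immunopurified library, to 6 significant digits, ranged from 24526800 to 75220900, and the input held 40912200. Counting intervals are exact Poisson intervals at the 95% level, and a count of 0 was read as at most 3 counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

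The groups were compared in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit, trimmed mean of M-values scaling). Genes were kept by edgeR's filter for the 3 treatment groups (minimum count 10, minimum total 15), which left 14989 of the 22641 genes with a count in any immunopurified library. All 9 immunopurified libraries entered 1 fit with 6 residual degrees of freedom. Cocaine was compared with saline, cocaine with yoked and yoked with saline, and 1 further test asked for any difference among the 3 groups. p values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels per group are normalised read counts scaled to library size (CPM) with the SD over 3 libraries.

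A total of 40 gene lists was fixed before the data were examined, of which 13 hold cell type markers and the others neuronal signalling, activity, stress, metabolic and RNA-quality genes. Lists with at least 3 measured genes were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, by camera with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the lists of a comparison. The level of each list per library was the mean over its genes of log2 CPM minus the gene's mean over the 9 libraries, compared between groups by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

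Immunopurified RNA was set against the input as the log2 ratio of CPM in each of the 3 saline immunopurified libraries to the 1 input library, with mean and SD. Genes with fewer than 20 counts both in the input and in the mean immunopurified library were left out. The input has no replicate, so no p value per gene was computed from these ratios. The median of each list was placed among 10000 random lists of the same size, matched on mean expression. The relation between the fold changes of cocaine and yoked against the shared saline libraries was compared with 100 simulated pairs of unchanged groups.

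The rule for naming genes was also fixed before the data were examined. In each treatment comparison it takes Chat, Slc18a3, Slc5a7 and Rpl10a, then the called genes with non-overlapping groups and a mean of at least 5 CPM or, with fewer than 10 of these, the 5 genes with the smallest p in each direction, named as not passing. Of a described list it takes up to 4 called members or, with none called, up to 2 with the smallest p. Against the input it takes the 12 highest and the 8 lowest ratios among genes with at least 100 counts on the higher side, and up to 4 members of each cell type list. Genes named outside this rule are said to be so.

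The edgeR steps were tested on simulated counts for 14989 genes. In these, 100 genes were changed 2-fold, 100 were changed 4-fold and a list of 30 was shifted by 0.5 on the log2 scale. The changed and shifted genes were drawn from those of at least 5 CPM, so the shares called do not cover genes below that level. Of the 2-fold changes, 46% were called for cocaine against saline, 43% for cocaine against yoked and 39% for yoked against saline; for the 4-fold changes the shares were 92%, 91% and 89%. False calls, counted outside the changed genes and the shifted list, numbered 12 of 153, 13 of 149 and 8 of 139. The counts were drawn independently for each gene and library, without pairing by number or libraries of another composition. Unchanged genes had an unadjusted p under 0.05 in 4.91, 4.59 and 4.51% of cases, against 5.28, 2.61 and 2.18% of genes in the real fits. The simulated shares may therefore overstate what the real comparisons with yoked could call.

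Groups share replicate numbers 1 to 3, and the labels do not say what a number marks. Whether the numbers pair the samples was checked by the correlation, over all tested genes, of same-numbered libraries' deviations from their group means. It was 0.130 to 0.177 between saline and yoked and 0.107 to 0.153 between cocaine and yoked, over the bound of 0.1 for all 3 pairs in both, so in these comparisons the numbers were taken to pair the samples. The planned main fits held no term for replicate number, so the main values reported for these comparisons ignore the pairing. Calls that the term changed are given beside them. Between cocaine and saline the correlation was 0.0776 to 0.107, with 1 of 3 pairs under the bound, so the check did not settle pairing there. Numbers that pair both groups with yoked would also pair them with each other. Lists called there with a term for replicate number are therefore given as well. Reading the check for each comparison in place of all 9 pairs together was adopted after the calls of both fits were seen.

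Alternatives were relative log expression scaling, no filter, a minimum mean of 5 CPM, a non-robust fit, a term for replicate number, a purification covariate, genes above the input only, sex-linked genes left out, fits of the 6 compared libraries alone, DESeq2 1.42.0, and leaving out each library in turn. For the ratios to the input an edgeR fit of all 10 libraries was also run; its ratios were used, and its calls were not, since the input has no replicate. For any difference among the 3 groups DESeq2 was run as a likelihood ratio test in place of the planned Wald test, which compares pairs. Added after seeing the data were fits without the 3 libraries numbered replicate 2, limma voom with library quality weights, and DESeq2 on genes with over 10 counts. The input library was left out of the treatment comparisons because it is another kind of RNA.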

Results

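Ribosome-bound RNA of striatal cholinergic neurons, the interneurons that supply the striatum with acetylcholine, was sequenced from mice that self-administered saline, from mice that self-administered cocaine and from yoked controls, with 3 immunopurified libraries per group. An input library of total striatal RNA from saline animals had no replicate. Gene counts, to 6 significant digits, were 25609300, 31426700 and 42100800 in saline libraries 1 to 3, 24526800, 75220900 and 29483900 in the cocaine libraries, 54980400, 30369100 and 27474700 in the yoked libraries and 40912200 in the input. Between 16530 and 18917 genes had a count in each immunopurified library and 20719 in the input. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 10 libraries, from 7.24 CPM upwards, and Xist, which marks the inactive X chromosome, lay at or below 1.32 CPM in each. The labels give lane 3 for the saline libraries, lane 4 for cocaine and yoked and lane 5 for the input, so lane and group cannot be told apart in comparisons with saline or with the input.

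The comparison of immunopurified RNA with the input asked how far the purification selected cholinergic RNA. All 12 measured cholinergic neuron markers were higher in immunopurified RNA, with a median log2 ratio of 5.33 ± 0.15 (SD of the library medians, n = 3), a 40.2-fold difference, at percentile 100 of random lists matched on expression. Slc18a3, the vesicular acetylcholine transporter, measured 8.36 CPM in the input and 884 ± 201 CPM (SD, n = 3) after purification, 104-fold higher. Ecel1 was 62.5-fold and Slc10a4, an orphan transporter of synaptic vesicles, 54.7-fold higher. Chat, the enzyme that makes acetylcholine (chromosome 14, 32408203 to 32465909, mm10), measured 10.1 CPM in the input and 550 ± 65.1 CPM after purification, 54.2-fold higher. Slc18a3 (chromosome 14, 32462437 to 32464850) lies inside Chat, so their reads may not be told apart where they overlap.

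Markers of the other cell types were lower in immunopurified RNA. The median log2 ratio was −3.24 ± 0.74 for 8 markers of D1 spiny projection neurons, −2.99 ± 0.56 for 5 of D2 spiny neurons and −3.13 ± 0.60 for 14 of spiny neurons in general (SD of the library medians, n = 3). It was −4.12 ± 0.37 for cortical glutamatergic neurons, −3.08 ± 0.63 for astrocytes, −3.30 ± 0.59 for oligodendrocytes, −3.44 ± 0.74 for oligodendrocyte precursors and −3.47 ± 0.45 for microglia. For other striatal interneurons it was −2.78 ± 0.25, for endothelial and mural cells −2.87 ± 0.28, for ependyma and choroid plexus −2.34 ± 1.90 and for blood −2.55 ± 0.32. The endothelial, ependymal and blood medians lay at percentiles 7.26, 7.83 and 39.98 of matched random lists, and the others at or below 0.23. Penk, the enkephalin precursor of D2 spiny neurons, measured 859 CPM in the input and 97.2 ± 41.9 CPM after purification, and Cnp, a myelin enzyme, 268 and 75.4 ± 31.9 CPM. Single markers went the other way, among them Lhx6 (log2 ratio 2.08 ± 0.44), a transcription factor of interneurons, Pdgfra (1.35 ± 0.17) of oligodendrocyte precursors and Chrm4 (1.05 ± 0.37) of D1 neurons.

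**Figure D1:**
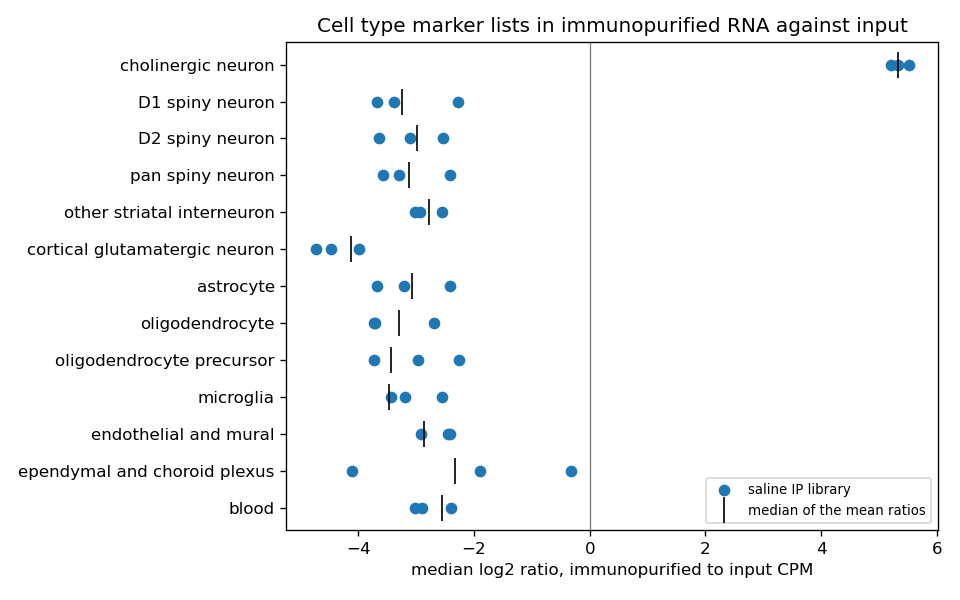
Median log2 ratio of immunopurified to input CPM (horizontal axis) for 13 lists of cell type markers; each point is 1 of the 3 saline immunopurified libraries against the same input library, and the vertical line is the median of the genes' mean ratios. The cholinergic list lies at 5.33 and the other 12 lists between −4.12 and −2.34.

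Across 15888 measured genes, 806 were at least 4-fold higher and 3185 at least 4-fold lower in all 3 saline immunopurified libraries. Among the highest ratios were Gm572 (220-fold, 4 input counts), AI606473 (83.9-fold, 59 input counts), Irf4 (80.7-fold, 8 input counts), Ooep (88.0-fold, 4 input counts) and AK030206 (80.3-fold, 5 input counts). Others rested on fewer input counts, for which the ratio of the mean immunopurified CPM is given: H2-M3 had 3, a ratio of 311 (95% counting interval 106 to 1509), Redrum 2, a ratio of 120 (33.3 to 994), Mamdc2 1, a ratio of 518 (92.9 to 20441), and Sln 1, a ratio of 325 (58.3 to 12832). Gm5868, with 0 input counts, was at least 158-fold higher, taking 3 counts as the floor, and the lower limit of its 95% counting interval was 128. The lowest ratios belonged to transcripts listed under sequence names. AK140265 measured 31487 CPM in the input and 106 ± 36.2 CPM after purification, 311-fold lower, and GU332589 188 and 0.311 ± 0.101 CPM, 631-fold lower. DQ539915, AK018753, BC071253, X57780 and AK163440 were between 117 and 191-fold lower, and AK162351 had about 1 count per immunopurified library against 439 in the input.

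Receptors and channels of the lists divided in this comparison. The dopamine receptor genes Drd5 and Drd2 were 37.1-fold and 5.27-fold higher in immunopurified RNA, and the muscarinic receptor Chrm2 14.9-fold higher. The neurokinin receptor Tacr3 was 35.5-fold, the delta opioid receptor Oprd1 11.7-fold, and the pacemaker channels Hcn3 and Hcn4 21.3-fold and 20.7-fold higher. The median over the 21 opioid and neuropeptide receptors was lower, at a log2 ratio of −2.58 ± 0.12 (SD of the library medians, n = 3), with 7 of them above the input in all 3 libraries and 13 below it. The 12 dopamine and acetylcholine receptors had a median of −0.58 ± 0.69, at percentile 42.5 of matched random lists, with 4 above the input and 6 below it, and the 26 pacemaker and potassium channel genes of −0.57 ± 0.16, at percentile 0.11 of matched random lists, with 8 of them above the input in all 3 libraries and 15 below it. These receptors and channels were chosen after their values were seen.

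Cocaine against saline self-administration asked which ribosome-bound transcripts of cholinergic neurons differ after taking the drug. The cholinergic transcripts showed no difference beyond the spread between libraries. Chat measured 632 ± 90.5 CPM after cocaine and 551 ± 67.5 CPM after saline (SD, n = 3), Slc18a3 725 ± 306 and 886 ± 212 CPM, and Slc5a7, the choline transporter, 1248 ± 232 and 1377 ± 167 CPM. The 95% interval of the log2 fold change was −0.15 to 0.55 for Chat, −0.90 to 0.33 for Slc18a3 and −0.53 to 0.24 for Slc5a7. Without the 3 libraries numbered replicate 2, the log2 fold change of Slc18a3 turned from −0.29 to 0.033. Rpl10a, whose coding sequence is also in the tag, measured 9.83 ± 3.49 and 6.02 ± 3.74 CPM, and its reads may be shared with pseudogenes and the transgene.

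No gene passed: 0 of 14989 were called by edgeR's quasi-likelihood test, whose smallest Benjamini-Hochberg adjusted p was 0.850, and 791 had an unadjusted p under 0.05 (414 higher, 377 lower, 5.28% of those tested). DESeq2 on the same genes called 0 (smallest adjusted p = 0.506), and limma voom with library quality weights called 0. DESeq2 on genes with over 10 counts called 1, AK140583, named after its values were seen, and edgeR without a filter on low counts called 60. The 3 libraries of a group lay wholly above or below the others in 10.5% of genes, where chance gives 10% if replicate number does not set libraries apart. For genes of at least 5 CPM the median interval reached 0.50 on the log2 scale to each side, or 1.42-fold.

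The genes with the smallest p are named as not passing, each with an adjusted p of 0.850 in edgeR with Benjamini-Hochberg adjustment. Toward higher levels after cocaine, Fyco1, an adaptor of autophagosome transport, measured 16.6 ± 5.84 against 6.22 ± 0.672 CPM. Dlx5, a homeobox factor of forebrain interneurons, measured 65.4 ± 12.3 against 38.1 ± 8.65 CPM, Klf7 42.5 ± 31.5 against 15.2 ± 3.39 and 1810055G02Rik 30.7 ± 19.98 against 11.7 ± 2.93. Ifi27l2a was near the floor in saline, at 0.732 ± 0.155 against 0.00812 ± 0.0141 CPM. Toward lower levels, Msmo1, a sterol synthesis enzyme, measured 29.1 ± 1.54 against 55.6 ± 19.0 CPM, Steap2 10.4 ± 2.90 against 22.9 ± 10.01, Ept1 41.4 ± 7.42 against 75.4 ± 27.5, Tmem30a 268 ± 46.0 against 422 ± 69.4 and Pla2g15 7.24 ± 2.60 against 24.0 ± 21.1. Without the 3 libraries numbered replicate 2, the log2 fold change of 6 of these 10 genes shrank by over 1.5 times. Klf7, at 78.6 CPM in cocaine library 2 against 27.6 and 21.2 in the others, went from 1.49 to 0.54, and 1810055G02Rik, at 53.7 against 20.5 and 17.8, from 1.40 to 0.55. Pla2g15, at 48.1 CPM in saline library 2 against 8.87 and 15.1, went from −1.73 to −0.56, Steap2 from −1.14 to −0.50, Ept1 from −0.87 to −0.38 and Tmem30a from −0.66 to −0.39.

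None of the 38 tested gene lists passed in this comparison without a term for replicate number. With it, oligodendrocyte markers (camera adjusted p = 0.00574), chromatin genes (0.0238) and cholesterol synthesis (0.0238) passed, with 0.767 for each at an estimated correlation. Of 17 cholesterol synthesis genes, 12 were lower and 5 higher (median log2 fold change −0.23, camera adjusted p = 0.180). Msmo1 was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0372, edgeR with Benjamini-Hochberg), and 0 passed over all genes. Adjustment over a list alone does not allow for the 38 lists, in which Msmo1 was the 1 member to pass so. Of 11 oligodendrocyte markers 9 were higher (median 0.36, camera adjusted p = 0.120), and of 30 chromatin and DNA methylation genes 23 were higher (median 0.23, camera adjusted p = 0.1096). Beside them, 1793 genes outside the lists that were at least 4-fold lower in immunopurified than in input RNA had a median log2 fold change of 0.38, and 72.8% of them were higher after cocaine. The median was 0.24 among those of at least 5 CPM. These genes were chosen by low values in the same saline libraries, which favours a rise against saline. Immediate early genes, which neurons induce on activity, were balanced, with 12 higher and 11 lower of 23 (median 0.0077, camera adjusted p = 0.629). The list was called higher without saline library 1 (camera adjusted p = 0.0351, and 0.711 with an estimated correlation). Nr4a2 had its smallest p, with a log2 fold change of 1.02 ± 0.43 (SE). Drd2, the D2 dopamine receptor that cholinergic neurons carry, measured 2560.5 CPM in cocaine library 2 against 1040.4 and 1193 in the other 2, with a log2 fold change of 0.65 ± 0.27 (SE), and the serotonin receptors Htr2c and Htr1a of −0.63 ± 0.20 and −1.07 ± 0.40; none of these passed. Without the 3 libraries numbered replicate 2 the value was 0.12 for Drd2, 0.63 for Nr4a2 and −0.53 for Htr1a. Without saline library 1, and likewise without cocaine library 2, 7 lists were called, among them oligodendrocyte markers (adjusted p = 9.9e-05 and 0.00292), chromatin genes (0.0355 and 0.0133) and cholesterol synthesis (0.00357 and 9.1e-04). With an estimated correlation the adjusted p of these 3 lists was 0.978 with all libraries, 0.711 to 0.744 without saline library 1 and 0.664 without cocaine library 2. Without saline library 3 or cocaine library 1, 1 list was called, and 2 were called without the 3 libraries numbered replicate 2. These 2 were the nuclear-encoded respiratory chain (45 of 75 lower with all libraries, median −0.073, camera adjusted p = 0.199, and 5.8e-04 without the 3) and the circadian clock (12 of 16 higher, median 0.28, 0.199 and 0.0357). Their adjusted p without the 3 was 0.912 with an estimated correlation. In that fit the oligodendrocyte, chromatin and cholesterol lists had camera adjusted p values of 0.0758, 0.306 and 0.0758 and medians of 0.36, 0.10 and −0.15.

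**Figure D2:**
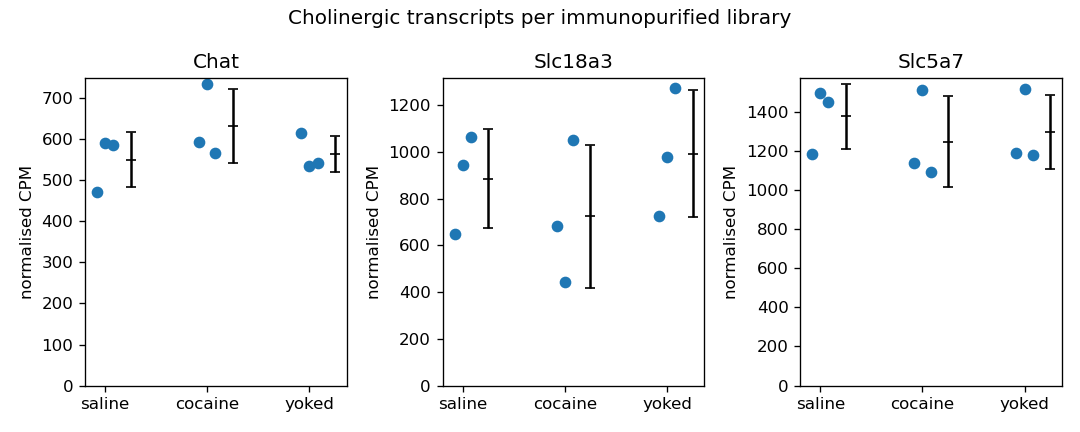
Normalised CPM (vertical axis, from 0) of Chat, Slc18a3 and Slc5a7 in each of the 9 immunopurified libraries; points are single libraries, and bars beside them show the group mean with 1 SD (n = 3). The groups overlap for each of the 3 transcripts, with Chat means of 551, 632 and 564 CPM.

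Cocaine self-administration against yoked controls compared animals that took the drug with controls sequenced under the same lane number. Chat measured 632 ± 90.5 and 564 ± 43.9 CPM (SD, n = 3), Slc18a3 725 ± 306 and 993 ± 273 CPM, Slc5a7 1248 ± 232 and 1295 ± 190 CPM, and Rpl10a 9.83 ± 3.49 and 8.98 ± 3.39 CPM. Of these, Slc5a7 (log2 fold change −0.054) turned to 0.0090 without cocaine library 1, 0.036 without cocaine library 3 and 0.076 without yoked library 2, and Rpl10a (0.13) to −0.062, −0.019 and −0.020 without cocaine library 1, yoked library 1 or yoked library 2. Zbtb38, a zinc finger protein that binds methylated DNA, had the smallest p and measured 173 ± 26.5 CPM after cocaine and 92.4 ± 20.4 CPM in yoked animals (log2 fold change 0.91, 95% interval 0.49 to 1.33, adjusted p = 0.9997 in edgeR with Benjamini-Hochberg). All 3 cocaine libraries lay above all 3 yoked libraries for this gene. Its highest level was 204 CPM in cocaine library 2 and its lowest 69.8 CPM in yoked library 2. Without the 3 libraries numbered replicate 2 its log2 fold change was 0.61.

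No gene passed: edgeR's quasi-likelihood test called 0 of 14989, 391 had an unadjusted p under 0.05 (245 higher, 146 lower, 2.61%), and non-overlapping groups made up 6.99% of genes. Chance gives 10% if replicate number does not set libraries apart, which does not hold strictly here. DESeq2 on the same genes (smallest adjusted p = 0.253) and limma voom with library quality weights each called 0, DESeq2 on genes with over 10 counts called 1, Il12a, named after its values were seen, and edgeR without a filter called 27. Others among the smallest p, also not passing, were CK137956 (16.9 ± 7.42 against 7.47 ± 2.77 CPM) and Lcat (4.47 ± 4.41 against 0.333 ± 0.239) toward higher levels. Toward lower levels they were AK038852 (9.81 ± 1.78 against 22.3 ± 10.2 CPM), Ficd, an enzyme that modifies the endoplasmic reticulum chaperone BiP (5.62 ± 1.18 against 11.8 ± 1.83), and Plxna3, a semaphorin receptor subunit (11.5 ± 1.76 against 21.5 ± 5.58). Without the 3 libraries numbered replicate 2 the log2 fold change went from 1.18 to 0.55 for CK137956, from 3.74 to 2.18 for Lcat and from −1.19 to −0.67 for AK038852. Crybb3 in yoked libraries (0.0227 CPM) and Calb2 in cocaine libraries (0.0222 CPM) were near the floor, and AK043467 was listed at 0 in all 3 cocaine libraries and at 0.427 CPM in the yoked group.

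Replication-dependent histone genes, whose messages lack a poly(A) tail, were lower after cocaine than in yoked animals, with 27 of 36 lower and 9 higher (median log2 fold change −0.42, camera adjusted p = 0.00473). With an estimated correlation the adjusted p was 0.968, and no member passed, over all genes or adjusted over the list alone; Hist2h2be had a log2 fold change of −0.78 ± 0.41 (SE) and Hist1h2ak of −1.07 ± 0.73, which were −0.29 and −0.45 without the 3 libraries numbered replicate 2. The camera call was lost without cocaine library 2 (adjusted p = 0.570), cocaine library 3 (0.440) or yoked library 1 (0.377), and without the 3 libraries numbered replicate 2 (0.144), where the median of the list was −0.042. Within replicate numbers 1, 2 and 3 the level of the histone list differed by 0.089, −0.85 and −0.52. The other 37 lists did not pass. Neurod6, a marker of cortical glutamatergic neurons, had a log2 fold change of 1.94 ± 0.82 (SE), with 5 of the 6 markers higher (camera adjusted p = 0.202). That list was called with a term for replicate number (adjusted p = 0.0194, which raised the count of lists from 1 to 2), without yoked library 2 (0.00266) and without the 3 libraries numbered replicate 2 (0.0101). With an estimated correlation its adjusted p was 0.968 with all libraries and 0.821, 0.969 and 0.978 in these 3 fits. Drd2 had a log2 fold change of 0.69 ± 0.27 (SE), also without passing, and of 0.10 without those 3 libraries; its highest level was the 2560.5 CPM of cocaine library 2. Its list, the 12 dopamine and acetylcholine receptors, was called lower without those 3 libraries (median −0.21, camera adjusted p = 0.0446, and 0.978 with an estimated correlation). With all libraries the camera adjusted p of that list was 0.866.

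Yoked controls against saline self-administration completed the pairs. Chat measured 564 ± 43.9 and 551 ± 67.5 CPM (SD, n = 3), Slc18a3 993 ± 273 and 886 ± 212 CPM, Slc5a7 1295 ± 190 and 1377 ± 167 CPM, and Rpl10a 8.98 ± 3.39 and 6.02 ± 3.74 CPM. The fold of Chat (log2 0.034) turned to −0.065 without saline library 1 and −0.034 without yoked library 1, that of Slc18a3 (0.16) to −0.017 without saline library 1 and −0.054 without yoked library 3, and that of Slc5a7 (−0.089) to 0.033 with a purification covariate. The 14 markers of spiny projection neurons were all higher in yoked libraries (median log2 fold change 0.17, camera adjusted p = 0.0355). Of 11 markers of other striatal interneurons, 8 were higher and 3 lower (median 0.76, camera adjusted p = 0.0114). With an estimated correlation the adjusted p was 0.936 for the spiny list and 0.344 for the interneuron list. Within replicate numbers 1, 2 and 3 the level of the spiny list differed by −0.16, 0.46 and 0.85, so it was lower in yoked library 1 than in saline library 1, and that of the interneuron list by 0.66, 1.45 and 0.63. Beside them, the 1793 genes at least 4-fold lower in immunopurified than in input RNA had a median log2 fold change of 0.38, and 73.6% of them were higher in yoked libraries. These genes were chosen by low values in the same saline libraries, which favours a rise against saline. In cocaine against yoked their median was −0.0029 and 49.9% were higher.

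Gng7, a G protein subunit of spiny neurons, had the smallest p of its list (log2 fold change 0.52 ± 0.22, SE), and among the interneuron markers Nos1, nitric oxide synthase, had a log2 fold change of 1.38 ± 0.58 (SE). Htr3a, a serotonin-gated channel, was near the floor, at 0.699 ± 0.719 CPM in yoked libraries and 0.0244 ± 0.0422 in saline libraries. No member of either list passed. Oligodendrocyte markers were higher in 10 of 11 cases without passing (median 0.47, camera adjusted p = 0.0654). They passed with a term for replicate number (adjusted p = 0.0017), without saline library 1 (1.3e-05) and without yoked library 2 (9.2e-04). With an estimated correlation their adjusted p was 0.936 with all libraries and 0.708, 0.593 and 0.779 in these 3 fits. The term for replicate number raised the count of called lists from 2 to 5, the others added being chromatin and DNA methylation genes (median 0.15, adjusted p = 0.0746 without the term and 0.0351 with it) and cytosolic ribosomal protein genes (median 0.10, 0.152 and 0.0351). With an estimated correlation both had an adjusted p of 0.936 without the term and 0.708 with it. Of the other cell types, the 8 endothelial and mural markers had a median of 0.51 with 7 higher (0.0058 without the 3 libraries numbered replicate 2), D1 and D2 spiny markers 0.19 and 0.20, oligodendrocyte precursors 0.0090, astrocytes −0.083, microglia −0.0996 and cortical neurons −0.12. Nuclear-retained RNAs were higher in 6 of 7 cases (median 0.39, camera adjusted p = 0.0766). None of these lists passed. The spiny call was lost without saline library 2 (adjusted p = 0.440) or 3 (0.653), cocaine library 2 (0.0509) or 3 (0.0598), or yoked library 1 (0.248) or 3 (0.323), and the interneuron call without cocaine library 2 (0.0509), yoked library 2 (0.0524) or yoked library 3 (0.0699). Without the 3 libraries numbered replicate 2 the adjusted p was 0.0492 and 0.282, and the nuclear-encoded respiratory chain (60 of 75 lower, median −0.051, camera adjusted p = 0.0956 with all libraries) was called at 0.0025, or 0.942 with an estimated correlation. Aif1, a microglial marker, passed when adjusted over its list alone (log2 fold change 2.06, adjusted p = 0.0182, edgeR with Benjamini-Hochberg), with 0 called over all genes. That adjustment does not allow for the 38 lists, in which Aif1 was the 1 member to pass so.

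No gene passed: edgeR's quasi-likelihood test called 0 of 14989, 327 had an unadjusted p under 0.05 (207 higher, 120 lower, 2.18%), and groups did not overlap in 7.28% of genes. Chance gives 10% if replicate number does not set libraries apart, which does not hold strictly here. DESeq2 on the same genes (smallest adjusted p = 0.0502) and limma voom with library quality weights each called 0, DESeq2 on genes with over 10 counts called 1, Gpr101, and edgeR without a filter called 18. Gpr101, an orphan receptor, measured 3.97 ± 1.84 CPM in yoked and 0.466 ± 0.175 CPM in saline libraries (log2 fold change 3.08 ± 0.70 SE, adjusted p = 0.999 in edgeR with Benjamini-Hochberg). Also not passing were Ipcef1 (8.16 ± 2.53 against 2.26 ± 0.615 CPM) and Rilpl2 (9.13 ± 3.80 against 2.86 ± 1.10) toward higher levels, and Ccdc65 (3.17 ± 1.62 against 13.0 ± 8.81), Creb3l1, a transcription factor of secretory cells (4.203 ± 0.163 against 8.46 ± 1.14), and Gm572 (11.7 ± 2.41 against 21.8 ± 4.63) toward lower levels. Without the 3 libraries numbered replicate 2 the log2 fold change went from 1.67 to 1.003 for Rilpl2, from −2.04 to −0.97 for Ccdc65, whose saline library 2 held 23.2 CPM, and from −0.90 to −0.54 for Gm572. Ifi27l2a (0.00812 CPM) and Grpr (0.0557 CPM) in saline and Iigp1 (0.0307 CPM) and 4921513D11Rik (0.123 CPM) in yoked libraries were near the floor. Fosb, an immediate early gene, measured 3.88 ± 1.74 against 0.972 ± 0.450 CPM without passing (log2 fold change 1.997, and 1.29 without the 3 libraries numbered replicate 2). Of the 23 immediate early genes 13 were higher (camera adjusted p = 0.204). Their list was called higher without saline library 1 (camera adjusted p = 0.00129, and 0.578 with an estimated correlation).

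The test for any difference among the 3 groups called 0 of 14989 genes in edgeR's quasi-likelihood fit (smallest Benjamini-Hochberg adjusted p = 0.9995), with 419 at an unadjusted p under 0.05 (2.80%). It called 0 in DESeq2's likelihood ratio test and 98 in edgeR without a filter. Across genes, which are not independent replicates, the log2 fold changes of cocaine and of yoked against saline correlated with r = 0.583 (Spearman's rho 0.510, 14989 genes). The shared saline libraries alone gave a mean r of 0.501 (0.468 to 0.541) in 100 simulated pairs of unchanged groups. The covariance was 0.234 against a simulated mean of 0.201 (0.178 to 0.229). At genes of at least 5 CPM r was 0.545, above the simulated 0.480 to 0.529, and the covariance of 0.0462 lay within the simulated 0.0416 to 0.0485. At an unadjusted p under 0.05, 70 genes were higher in both comparisons and 30 lower in both. Both comparisons use the same saline libraries, which cannot be divided between them and favour such overlaps.

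The 3 libraries numbered replicate 2, 1 in each group, differed from the other 6 in composition. The ribosomal RNA precursor Rn45s took 1.40 to 3.34% of their gene counts against 10.6 to 15.99%, and after thinning to equal totals they held 16203 to 16450 genes against 17354 to 18611. Their mean correlation with the other immunopurified libraries was 0.933 to 0.935 against 0.954 to 0.960. Without them edgeR called 0 genes in each of the 3 pairs, with 525, 199 and 457 at an unadjusted p under 0.05 for cocaine against saline, cocaine against yoked and yoked against saline.

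**Figure D3:**
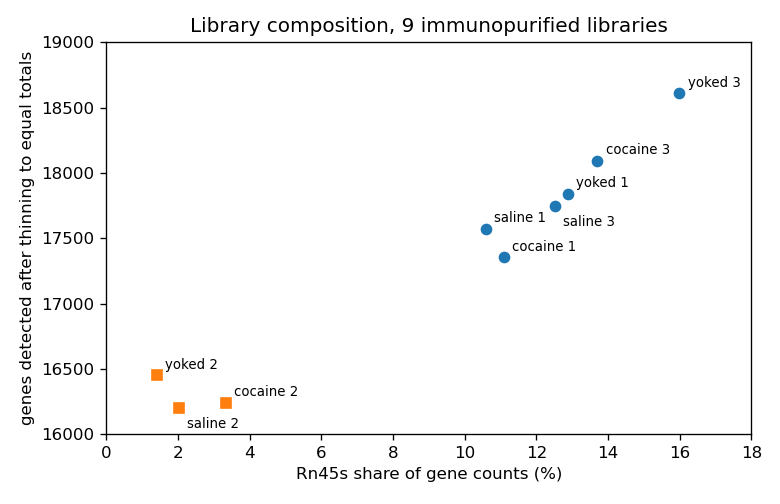
Share of gene counts taken by Rn45s (horizontal axis, percent) and number of genes with a count after thinning to 24526800 counts (vertical axis, not from 0) in the 9 immunopurified libraries; squares are the libraries numbered replicate 2 and circles the other 6. The squares lie at 1.40 to 3.34% and 16203 to 16450 genes, apart from the circles.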

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

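Fits without the 3 libraries numbered replicate 2, voom with quality weights and DESeq2 on genes with over 10 counts were chosen after seeing the data; the other alternatives were planned, and all were run as planned except DESeq2 for any difference, run as a likelihood ratio test in place of the Wald test. The count of called genes stayed 0 in 73 alternative fits, with 7 exceptions. These were edgeR without a filter on low counts, which called 60 genes for cocaine against saline, 27 for cocaine against yoked, 18 for yoked against saline and 98 for any difference, and DESeq2 on genes with over 10 counts, which called 1, 1 and 1 for the 3 pairs. Without the filter the estimated prior degrees of freedom were infinite for all 22641 genes, against a median of 8.15 with it, so no gene kept a spread of its own. Of the 10 genes per comparison taken for the smallest p, 6, 2 and 1 were among these calls, such as Klf7 and Pla2g15, Zbtb38, and Ccdc65; 53, 24 and 11 of the calls were genes also tested with the filter, and 23, 5 and 4 had groups that did not overlap. With DESeq2 the cause was not tested. Leaving out 1 library at a time moved the count of genes at an unadjusted p under 0.05 in edgeR. It ranged from 328 to 1114 for cocaine against saline, 131 to 900 for cocaine against yoked and 209 to 593 for yoked against saline.

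The list counts were 0, 1 and 2 for cocaine against saline, cocaine against yoked and yoked against saline. They were 0, 0 and 0 with an estimated correlation and with fry, and 0 of the 60 list calls of the alternatives held with an estimated correlation (lowest adjusted p = 0.473). They were 3, 2 and 5 with a term for replicate number, and 2, 2 and 2 without the 3 libraries numbered replicate 2; the cause was not tested. The term for replicate number changed no other call of a list or named gene in the 2 comparisons with yoked. With it edgeR called 0 genes in both, with 448 at an unadjusted p under 0.05 for cocaine against yoked and 398 for yoked against saline. In cocaine against saline, where the check did not settle pairing, each library still correlated best with its own number. Over all 3 groups the lowest correlation of same-numbered libraries, 0.0776, lay above the highest of the others, 0.0573. The lists called in cocaine against saline with the term were oligodendrocyte markers (camera adjusted p = 0.00574), chromatin genes (0.0238) and cholesterol synthesis (0.0238). Leaving out 1 library at a time gave 0 to 7, 0 to 3 and 0 to 6 lists. For cocaine against yoked it was 0 without cocaine library 3 or yoked library 1 and 3 without yoked library 2. For yoked against saline it was 6 without saline library 1, 4 without yoked library 2, 1 without cocaine library 3 and 0 without cocaine library 2 or yoked library 3. The exact permutation test of list levels gave p = 0.5 for the histone list in cocaine against yoked. It gave 0.4 and 0.1 for the spiny and interneuron lists in yoked against saline, with an adjusted p of 0.806 for both.

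Of the named genes' fold changes, 658 alternative values kept their direction and 12 did not, and no named gene passed as reported. Fits of the 6 compared libraries gave no value for Ifi27l2a and Iigp1 in yoked against saline, which their filter removed. Direction turned for Slc18a3 in cocaine against saline without the 3 libraries numbered replicate 2 (0.033) and Slc5a7 in yoked against saline with a purification covariate (0.033). Leaving out 1 library gave ranges of −0.21 to 0.076 for Slc5a7 and −0.062 to 0.48 for Rpl10a in cocaine against yoked, and −0.065 to 0.090 for Chat and −0.054 to 0.34 for Slc18a3 in yoked against saline. The 95% intervals of these folds include 0. The cholinergic ratio to the input stayed within 5.25 to 5.42 in all alternatives run. Over all 13 lists, 77 alternative ratios moved by less than the spread between libraries and 14 by more, these all in lists of other cell types and all still below 0. The correlation between the fold changes of cocaine and yoked against saline was 0.545 at genes of at least 5 CPM, against 0.583 over all. The depth and spread limit what can be seen. For genes of at least 5 CPM, changes under about 1.42-fold lie within the median unadjusted 95% interval. Larger changes can also go uncalled after adjustment. In the simulated counts 39 to 46% of 2-fold changes in genes of at least 5 CPM were called.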

Other observations

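Of the tests in this part, those of sequencing depth, of differences within replicate numbers and of splits that part all pairs were chosen only after the results were seen. Further gene groups differed between immunopurified and input RNA of the saline animals. Transcripts of the nuclear-encoded respiratory chain were higher after purification, with 73 of 75 above the input in all 3 libraries and a median log2 ratio of 1.46 ± 0.06 (SD of the library medians, n = 3), at percentile 100 of matched random lists. Cytosolic ribosomal protein transcripts (70 of 81, median 1.11 ± 0.29) and proteasome transcripts (34 of 37, median 0.83 ± 0.11) were higher as well, at percentiles 100 and 99.85. Nuclear-retained RNAs were lower in 7 of 7 cases (median −3.57 ± 0.81), and Malat1, a nuclear RNA, measured 21553 CPM in the input. Immediate early genes had a median of −2.47 ± 0.84, with 18 of 23 below the input in all 3 libraries. Circadian clock genes had a median of −1.61 ± 0.38 and glutamate receptors of −1.40 ± 0.09.

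Trophic factors and receptors known from cholinergic neurons were among the transcripts above the input. Ngfr was 17.9-fold, Ret 16.8-fold and Gdnf, a trophic factor of dopamine neurons, 10.03-fold higher, though the 12 genes of the neurotrophin list had a median log2 ratio of −1.62 ± 0.27 (SD of the library medians, n = 3), at percentile 0.33, with 4 above the input in all 3 libraries and 8 below it. S100a10, which encodes p11, was 8.06-fold higher, while its partners Ahnak and Anxa2 lay below the input. The glutamate receptor subunit Grin2d was 17.9-fold higher, with 4 of its 24 list members above the input and 18 below it, and the small heat shock protein Hspb1 33.5-fold, with 8 of 11 above and 2 below. The genes of this paragraph were chosen after their values were seen, and each ratio rests on the 1 input library.

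Kalrn, a synaptic exchange factor chosen after its values were seen, measured 1156 ± 317 CPM after cocaine and 708 ± 261 CPM after saline (SD, n = 3). Its log2 fold change was 0.71, and 1.26 without the 3 libraries numbered replicate 2, with an adjusted p of 0.850 and 0.9997 in edgeR with Benjamini-Hochberg. Ttr, a choroid plexus transcript, measured 88.0 CPM in saline library 3 and 17.0 CPM in yoked library 1, and at most 2.21 CPM in the other 7 immunopurified libraries.

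The 3 libraries numbered replicate 2 stood apart from the other 6 in the share of Rn45s and the number of genes, and no biological explanation was tested. Lower depth is argued against, since their totals of 30369100 to 75220900 counts were not below the 24526800 to 54980400 of the others, and after thinning to equal totals they held at most 16450 genes and the others at least 17354. Carry-over of RNA from other cells is argued against as the whole source by 4398 genes at like levels in input and immunopurified RNA, which it cannot move: their SD was at least 0.699 in the replicate 2 libraries and at most 0.390 in the others. A lower carry-over beside it stays open, since genes at least 4-fold lower after purification had levels of −0.98, −0.28 and −0.35 in these libraries against −0.17 to 0.56 in the others. Fewer distinct RNA molecules may be the source and stay open. The test took 4302 genes with a mean of 1 to 10 CPM in the other 6 libraries. After thinning, 0.930 to 1.70% of them were missing from the replicate 2 libraries, against at most 0.0930% from the other 6. Choosing the genes by their level in the other 6 favours such a difference, so it does not decide the question. The overlap of missing genes between pairs of the replicate 2 libraries was 2.58, 1.43 and 1.22 times chance, on 7, 5 and 2 genes.

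Spiny neuron and oligodendrocyte markers were higher in yoked than in saline libraries, the spiny list past the threshold of camera and the oligodendrocyte list not, except with a term for replicate number or without saline library 1 or yoked library 2. With an estimated correlation the camera adjusted p of both lists was 0.936. Carry-over of whole-striatum RNA is a candidate explanation, which the test set for it cannot decide. The 1793 other genes at least 4-fold lower in immunopurified than in input RNA had a median log2 fold change of 0.38, and 0.25 among those of at least 5 CPM. This is above the bound of 0.1, but the genes were chosen by low values in the same saline libraries, which favours a rise against saline. In cocaine against yoked, which holds no saline library, their median was −0.0029 and 49.9% were higher. Within replicate numbers 1, 2 and 3 the level of these genes was higher in yoked libraries by 0.13, 0.63 and 0.73 (two-sided exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow), while that of the spiny list differed by −0.16, 0.46 and 0.85, of oligodendrocyte markers by 0.10, 0.38 and 0.83, of oligodendrocyte precursors by 0.36, 0.29 and 0.15, of microglia by −0.80, 0.44 and 0.93, of nuclear-retained RNAs by −0.44, 0.60 and 0.51, of endothelial and mural markers by 0.56, 2.01 and −0.43, of astrocyte markers by −0.14, −0.72 and 0.56 and of cortical neuron markers by 0.081, 0.014 and −0.94. The pattern also rested on single libraries, with an adjusted camera p for the spiny list of 6.0e-07, 0.440 and 0.653 without saline library 1, 2 and 3, and saline library 2 had the lowest level of these genes, −0.98. Treatment and lane number coincide here, so both, and an effect of the yoked condition, stay open.

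Other splits of the libraries were counted for each model. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real gene counts of 0, 0 and 0 were reached in 10, 10 and 10 splits for cocaine against saline, cocaine against yoked and yoked against saline, with highest other counts of 2, 0 and 0. The real list counts of 0, 1 and 2 were reached in 10, 7 and 7 splits, with highest other counts of 14, 13 and 15. Counts several times the real one point to a structure of the samples: those of 14 and 15 grouped saline library 1 with libraries 1 and 3 of the other arm. Where the numbers pair the samples, 4 splits part all 3 pairs; among these the highest other list count was 1 for cocaine against yoked and 6 for yoked against saline, and with a term for replicate number 1 and 6 beside real counts of 2 and 5. The other 6 splits part 1 pair each and reached 13 and 15. For any difference among 3 groups, 100 of 100 drawn splits called as many genes as the real 0, with a highest other count of 20. Every split reaches a count of 0, so these shares decide nothing for the gene counts.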
